A study of Oryza sativa with 8 samples.

How the data were processed

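Messenger RNA levels were measured on 8 two-colour Agilent oligonucleotide arrays hybridised with RNA from the third leaf of seedlings of the japonica rice cultivar Nipponbare. Per the labels' protocols, seedlings were raised in a greenhouse of the institute NIES in Tsukuba and some were taken to Iitate Farm (ITF), a field with ground contamination by radiocaesium, where the dose rate was about 5 µSv/h. Inside the exposure boxes it was about 1.6, 2.6 or 4.2 µSv/h, depending on the shielding. The labels do not say from which box the hybridised RNA came, so no dose is attached to any value. For the gamma arrays the labels give leaves of 6 to 10 seedlings per sampling. No number is recorded here for the other arrays. Another label calls the plants mature, and the clock time of sampling is not given in the sources used here.

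The arrays formed 4 pairs. In each pair RNA of the same 2 conditions was hybridised with Cy3 and Cy5 exchanged (a dye swap). The pairs were ITF 0 h over NIES 0 h, NIES 72 h over NIES 0 h, gamma 6 h over ITF 0 h and gamma 72 h over ITF 0 h, where gamma means leaves taken that long after arrival at the farm and ITF 0 h is read here as arrival. The labels call each pair a dye swap and do not say whether both of its arrays used the same RNA extract. A pair was treated as the same 2 RNAs and counted as 1 replicate, which leaves 0 residual degrees of freedom. No test between conditions was made and no p-value is given, and the spread between the dye orientations is read as hybridisation error. If the extracts differed between the arrays of a pair, it would hold their differences as well. The description field of the NIES 72 h arrays names ITF 0 h as the partner, whereas the titles and source names give NIES 0 h. The titles were followed, and the partner was checked through the single-channel levels.

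Per the file headers, each scanner file holds 1 array read by Agilent Feature Extraction, version 11.0.1.1 per the submitters' processing notes. The deposited spot values are median foreground and background intensity in each channel on a linear scale, with processed intensity after Feature Extraction's own background subtraction and dye normalisation. The deposited files also give a log10 ratio of red (Cy5) over green (Cy3) made by Feature Extraction, which set it to 0 for 15.5 to 18.9% of the probes of an array. The authors' series table holds log10 ratios with no stated scale, centring or direction. Set against the scanner files, each of its columns equalled the log10 ratio of red over green processed intensity within 0.002 for 100% of the probes, so scale and direction are known. It was not centred further, with column medians of 0.036 and 0.045 (gamma 6 h, replicates 1 and 2), 0.033 and 0.015 (gamma 72 h), 0.023 and 0.012 (ITF 0 h), and 0.024 and 0.044 (NIES 72 h). All 8 of its columns were matched to an array.

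The log2 ratios used here were computed from the deposited spot intensities in R 4.3.3 with limma 3.58.1. Mean foreground signals had been planned for, but the files hold medians, so median signals were used. Background was corrected with normexp (offset 50) fitted on all spots including controls. Ratios were then normalised within each array by loess (span 0.3) with weight 0 for the control spots, which were left out afterwards. Spots marked by Feature Extraction as non-uniform or population outliers were left out (1 to 27 spots per array). No spot was saturated (0 on every array). Each ratio was turned to test over reference, and the 2 orientations were averaged. A locus was measured in a comparison if it was well above background on both arrays in at least 1 of the RNAs compared. For the 2 derived comparisons any RNA of the combined ratios sufficed, including the 0 h RNAs. Their measured loci thus include some above background in neither 72 h RNA. It was called higher or lower if its ratio was at least 2-fold in the same direction in both orientations. For a locus below background on both arrays of an RNA the ratio is a bound. No locus printed by name was in that position by the scanner's marks, but ratios of loci that were dim in 1 RNA depend on the offset. Loess fits a trend of the ratio with brightness and takes it out, though medians by brightness can still differ from 0 afterwards. If the composition of the RNAs differs with expression level, this moves the balance of higher and lower calls, so that balance is given with median centring as well.

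Depth on an array is the signal over background. The median Cy3 signal was 75 to 87 against a median background of 57 to 59.5, and the median Cy5 signal was 81 to 89 against 64 to 65. Between 48.4 and 57.7% of the 43494 probes were well above background in a channel. Of the spot channels of the negative controls, 0.0408% were. The number of arrays limits the precision. The gamma arrays lay on slide 1 and were scanned on day 1. The ITF 0 h and NIES 72 h arrays lay on slide 2 and were scanned on day 2. Every direct ratio is formed within an array, but no direct comparison spans both slides, so slide and comparison cannot be told apart. The 2 derived comparisons combine arrays of both slides and scan days.

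Of the probes, 41446 carry a locus identifier of the array's design, each locus having 1 probe, and 2048 carry an identifier with no locus. The files do not pair these identifiers with gene names or descriptions. The reference table of the assembly ASM3414082v1 matched 1 locus, which was not measured above background in any comparison. The 45 gene lists fixed in advance name genes by description or by 45 loci, of which 0 matched, so no list was evaluated. The rule for named genes took the most extreme called genes with a name and description. Without names it was applied to locus identifiers, limited to the 2 highest and the 2 lowest mean log2 ratios per comparison. Chromosomes were read from the identifier, and no coordinates are given.

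Further values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The change over 72 h at the farm less that in the greenhouse is the difference of the 2 log2 ratios per orientation. The indirect comparison of gamma 72 h with NIES 72 h is a sum of 3 ratios, since those RNAs never shared an array. Where comparisons share an RNA, the overlap was set beside that of independent lists and beside 100 simulations of 3 unrelated RNAs, 1 of them shared. In these the variance of each ratio was split evenly between its 2 RNAs, the shared RNA taking the mean over both ratios. The simulated correlation and covariance follow from that split, and a shared RNA of larger spread would raise their size. Simulated loci were called from a 2-fold mean ratio, a looser rule than 2-fold in both orientations. Simulated numbers of calls are therefore not like for like with the observed ones. With 1 RNA per condition the shared RNA cannot be split. Technical standard errors came from a limma fit of the 8 arrays with a dye term. Intervals of shares are 95% Wilson intervals over loci and do not cover differences between plants. Called neighbouring loci were compared with 1000 random placements within 20 brightness classes. Calling was tested on simulated data with 200 changed loci and noise pooled over the 4 direct comparisons. The recovery is therefore not specific to the noise of each comparison. All 3-fold changes were recovered in the 4 direct comparisons (100%). Recovery was 96.0% in the difference of 72 h changes and 94.0% in the indirect comparison. Between 0 and 3 unchanged loci were called.

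Alternatives fixed before the data were examined were no background correction, a normexp offset of 16, median centring, Feature Extraction's log ratio, the authors' table, filters on dim probes, outlier spots kept, other fold thresholds and call rules, each array left out, and separate-channel levels. Median centring combined with a 2-fold mean was added after seeing the data, since the dye trend left by median centring cancels in the mean of both orientations.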

Results

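The study asked how leaves of rice seedlings respond to low-level gamma radiation from contaminated ground. It compared leaf RNA after 6 h and 72 h at the contaminated farm (gamma 6 h and gamma 72 h) with leaf RNA at arrival there (ITF 0 h). Greenhouse plants were sampled at 0 h and 72 h (NIES 0 h and NIES 72 h). The 5 RNAs were hybridised in 4 dye-swapped pairs on 8 arrays, 2 arrays per comparison. Each condition was treated as 1 RNA, so the differences below have no replicate check across plants, and a fold change describes these RNAs. Between 21131 and 23224 loci were measured in each direct comparison. The correlation of the log2 ratios between dye orientations, across loci, was 0.94 to 0.98. No locus was at least 2-fold in opposite directions in the 2 orientations (0 in each comparison). The median technical standard error of a log2 ratio was 0.069 in the direct comparisons.

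The first comparison set ITF 0 h against NIES 0 h and so measured what already differed between seedlings at arrival and in the greenhouse. At arrival 840 loci were at least 2-fold higher and 982 were at least 2-fold lower, together 8.62% of 21131 measured loci. The median log2 ratio was 1.59 among the higher and −1.50 among the lower loci. LOC_Os07g37550 on chromosome 7 had the highest ratio, with a mean log2 of 7.59 (8.06 and 7.13 with the ITF RNA in Cy5 and in Cy3), or 193-fold. LOC_Os03g39610 on chromosome 3 followed at 6.78 (7.19 and 6.38), or 110-fold. The lowest ratios were those of LOC_Os04g02880 on chromosome 4 at −5.55 (−5.53 and −5.57) and LOC_Os02g46030 on chromosome 2 at −5.42 (−5.47 and −5.36). By chromosome, the share of measured loci called ran from 6.86% on chromosome 11 to 9.67% on chromosome 5. Higher loci made up 46.1% of the calls (95% interval over loci 43.8 to 48.4%), and 33.0% with median centring, which left 936 calls. Median centring with a 2-fold mean had 2445 calls.

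Greenhouse leaves at 72 h were compared with greenhouse leaves at 0 h, the change over the same time without the farm. Here 1556 loci were higher and 1663 lower, 14.6% of 21995 measured loci, with median log2 ratios of 1.69 and −1.64. The highest ratio was again that of LOC_Os07g37550, at 7.52 (8.31 and 6.72), followed by LOC_Os03g02020 on chromosome 3 at 6.47 (6.72 and 6.22), or 88.7-fold (7.57 with Feature Extraction's log ratios). LOC_Os04g02880 at −6.26 (−6.28 and −6.24; −7.29 with Feature Extraction) and LOC_Os03g04100 on chromosome 3, also at −6.26 (−5.97 and −6.54), were the lowest. By chromosome, called loci made up 12.7% on chromosome 12 and 15.8% on chromosome 3, the ends of the range. Higher loci were 48.3% of the calls, and with median centring 58.3%, so the side with more calls depended on the normalisation.

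The calls against NIES 0 h overlapped. Of the 20319 loci measured in both comparisons, 579 were higher in both ITF 0 h and NIES 72 h and 706 were lower in both, where independent lists would share 62.1 and 79.9. Only 15 were called in opposite directions. The shared loci were 71.3% of the loci called at arrival. The correlation of the log2 ratios across loci, which are not independent replicates, was 0.76, and the covariance was 0.492. NIES 0 h is the reference of both. For that reason alone, 3 unrelated RNAs with evenly split variance would give a correlation of 0.51 and a covariance of 0.339. They gave 1339 calls in the same direction, against 1285 observed, and 69 in opposite directions. Simulated calls needed only a 2-fold mean, so these numbers are not like for like. The covariance exceeded the simulated value by 0.153, but a shared RNA of larger spread than the even split assumes would raise that value. How much of the overlap comes from the shared RNA is therefore open, since it could not be split.

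**Figure D1:**
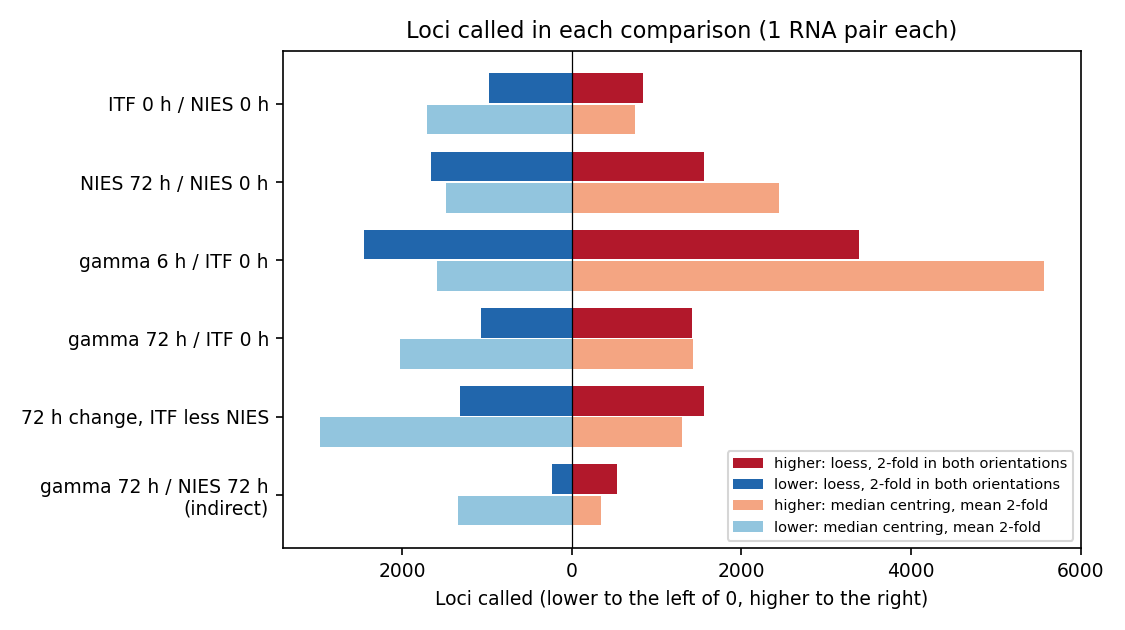
Loci called higher (bars to the right of 0) and lower (bars to the left) in the 4 direct and the 2 derived comparisons, as numbers of loci, with dark bars for loess with 2-fold in both dye orientations and light bars for median centring with a 2-fold mean. The gamma 6 h comparison has the most calls and the longest bar of higher loci under both (3389 and 5563), but its bar of lower loci is the longest under loess only (2452, against 1584 with median centring), and the side with more calls changes with the normalisation in 4 of the 6 comparisons.

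Gamma 6 h against ITF 0 h measured the first 6 h at the farm and had the most calls of the direct comparisons. Leaves at 6 h had 3389 higher and 2452 lower loci, 25.2% of 23224 measured loci. At least 8-fold changes were seen at 297 higher and 235 lower loci. LOC_Os02g05470 on chromosome 2 was highest at a mean log2 of 7.21 (7.73 and 6.68), or 148-fold, and LOC_Os11g32650 on chromosome 11 followed at 6.77 (7.47 and 6.07), or 109-fold. LOC_Os05g31140 on chromosome 5 was lowest at −7.48 (−7.54 and −7.42), and LOC_Os01g12270 on chromosome 1 followed at −6.90 (−6.80 and −6.99). The 6 h level of LOC_Os05g31140, a log2 of 5.65, lay at the floor set by the normexp offset of 50, so the size of its ratio depends on the processing: it was −8.28 with an offset of 16 and −10.05 with Feature Extraction's log ratios. With median centring LOC_Os02g05470 had 7.84, LOC_Os11g32650 7.40 and LOC_Os01g12270 −6.28.

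Of the higher loci at 6 h, 158 were below background on both arrays in the ITF 0 h RNA, and of the lower loci 68 were below background at 6 h. Ratios of these loci are bounds. Called loci were spread over all 12 chromosomes, from 21.8% on chromosome 10 to 27.5% on chromosome 3. Among the loci of the dimmer 50% by brightness 80.3% of the calls were higher, and among the brightest 10% of loci 38.1% were. Brightness was the mean over all 8 arrays, and ITF 0 h RNA was on more of them than gamma 6 h RNA. Loci low in ITF 0 h therefore tend to be classed as dim, which by itself favours higher calls there. In ITF 0 h over NIES 0 h, with ITF 0 h as the test RNA, the shares were 28.7% and 61.1%. Higher loci were 58.0% of all calls (56.8 to 59.3%), and 78.5% with median centring, which moved the median log2 ratio of all measured loci by 0.21. None of the arrays used here holds greenhouse RNA of 6 h, so the change over 6 h at the farm has no counterpart here.

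Gamma 72 h against ITF 0 h measured the change over 72 h at the farm. After 72 h, 1413 loci were higher and 1076 lower, 11.4% of 21871 measured loci, with median log2 ratios of 1.75 and −1.51. LOC_Os11g32650 was the highest at 6.99 (7.56 and 6.42), or 127-fold (7.62 with Feature Extraction), and LOC_Os07g08160 on chromosome 7 followed at 6.40 (6.77 and 6.03). LOC_Os05g28740 on chromosome 5 at −5.92 (−5.84 and −6.00) and LOC_Os01g03340 on chromosome 1 at −5.67 (−5.53 and −5.81) were the lowest. Chromosome 10 had the lowest share of called loci (9.38%) and chromosome 3 the highest (12.6%). Higher loci were 56.8% of the calls under loess but 38.1% under median centring, which left 1206 calls. Median centring with a 2-fold mean had 3457 calls. Without the array that held gamma 72 h in Cy3, 3897 loci passed the 2-fold threshold.

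Most loci called at 72 h had also been called at 6 h. Over the 21264 loci measured at both times, 926 were higher at both (220 in independent lists) and 863 were lower at both (124). These were 65.8% of the higher and 80.3% of the lower loci of 72 h. Conversely, 27.8% of the loci higher at 6 h and 35.2% of those lower at 6 h were still called at 72 h. Of the loci higher at 6 h, 1234 lay within 1.5-fold of ITF 0 h at 72 h, as did 508 of the lower ones. Among loci called at both times the median log2 ratio went from 2.25 at 6 h to 1.87 at 72 h for the higher and from −2.21 to −1.62 for the lower loci. LOC_Os02g05470 had log2 ratios of 7.21 and 6.08 at 6 h and 72 h and LOC_Os01g12270 −6.90 and −4.42. Calls in opposite directions were made at 52 loci, 51 of them lower at 6 h and higher at 72 h.

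The correlation of the 6 h and 72 h ratios across loci was 0.70, against 0.51 simulated for unrelated RNAs with a shared reference, and the covariance was 0.677 against 0.514. Such RNAs would also give 2322 calls in the same direction, against 1789 observed, and 170 in opposite directions, against 52. Simulated calls needed only a 2-fold mean, a looser rule than the observed calls met, so these numbers are not like for like. The simulated correlation and covariance rest on evenly split variance, and a shared RNA of larger spread would raise them. How much of the overlap comes from the ITF 0 h RNA is therefore open, since that RNA could not be split. The overlap was 897 loci with median centring and 4430 with Feature Extraction's log ratios.

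**Figure D2:**
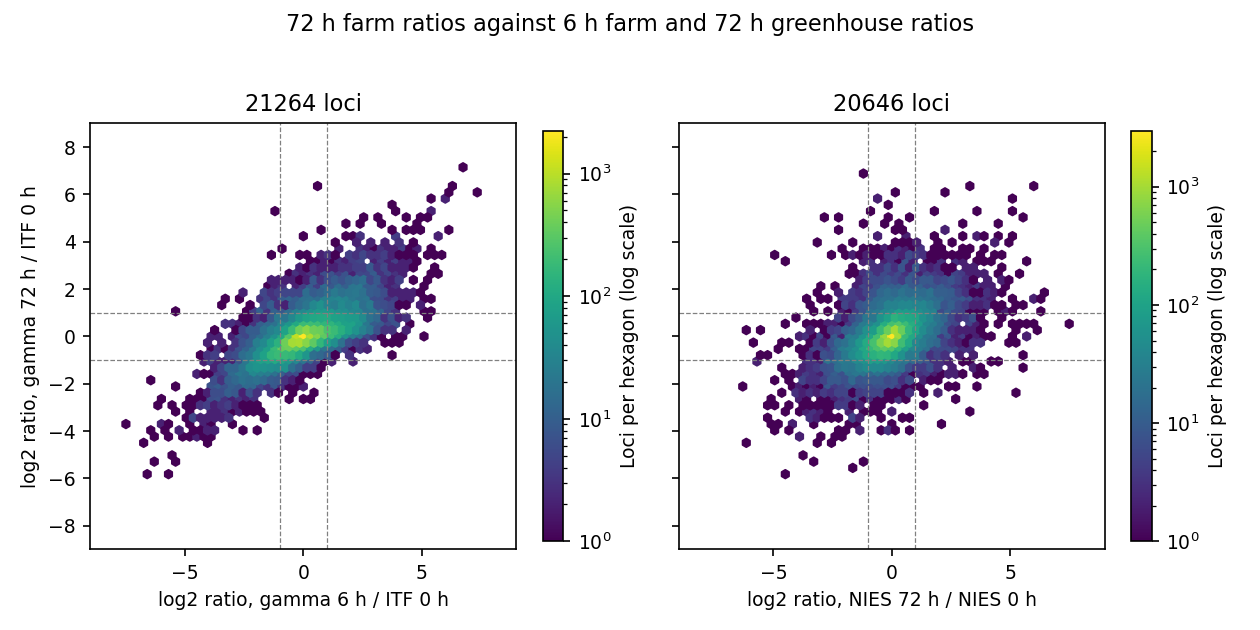
Log2 ratios of gamma 72 h over ITF 0 h (vertical axes) against those of gamma 6 h over ITF 0 h (left, 21264 loci, shared reference) and NIES 72 h over NIES 0 h (right, 20646 loci, no shared RNA), with colour giving the number of loci per hexagon on a log scale and dashed lines at 2-fold. The points lie closer to a line on the left (correlation 0.70 across loci) than on the right (0.47). On the left, unrelated RNAs with the shared reference would already give 0.51, so the 2 correlations are not like for like.

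The 72 h changes at the farm and in the greenhouse share no RNA. Over 20646 loci their log2 ratios had a correlation of 0.47 across loci and a covariance of 0.362. At both sites 590 loci were higher at 72 h (105 in independent lists) and 533 were lower (86.1), while 146 were called in opposite directions. The shared calls were 45.7% of the farm's and 34.9% of the greenhouse's. LOC_Os07g08160 had a log2 ratio of 6.40 at the farm and 5.90 in the greenhouse, and LOC_Os05g28740 had −5.92 and −4.57. Of the 1389 loci higher at the farm, 714 were not called in the greenhouse, and 619 were still called after its change was subtracted. Of the 1070 lower loci, 476 were not called in the greenhouse and 339 were still called after subtraction.

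The difference of the 72 h changes, each against its own 0 h RNA, was at least 2-fold in both orientations at 2866 of 23207 loci. It was higher at the farm for 1553 and lower for 1313. LOC_Os10g39150 on chromosome 10 had the highest difference at 8.42 (8.50 and 8.34), with a log2 ratio of 3.52 at the farm and −4.90 in the greenhouse. LOC_Os11g32650 followed at 8.27 (9.03 with Feature Extraction), with 6.99 and −1.27. LOC_Os04g21350 on chromosome 4 had the lowest at −7.70, with −2.36 at the farm and 5.35 in the greenhouse. LOC_Os07g37550 had −6.90 (−7.63 with Feature Extraction), with 0.61 at the farm and 7.52 in the greenhouse, and it was already 7.59 higher in ITF 0 h than in NIES 0 h. The difference includes whatever already differed between the 0 h RNAs. In ITF 0 h over NIES 0 h, LOC_Os10g39150 had −5.21, LOC_Os11g32650 −3.30 and LOC_Os04g21350 4.69. Higher loci were 54.2% of the calls under loess and 28.9% under median centring.

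Gamma 72 h and NIES 72 h, leaves taken 72 h after the 0 h sampling of each site, were compared through 3 ratios. Fewer loci differed than in any direct comparison: 531 were higher and 235 lower in gamma 72 h, 3.25% of 23541 loci. LOC_Os03g32470 on chromosome 3 was highest at 5.55 (5.73 and 5.36), and LOC_Os04g43800 on chromosome 4 followed at 5.27 (5.55 and 4.99). LOC_Os01g47070 on chromosome 1 at −4.65 (−4.83 and −4.48) and LOC_Os04g59150 on chromosome 4 at −4.24 (−4.28 and −4.19) were the lowest. The last had log2 ratios of −4.09 over 72 h at the farm and 0.23 in the greenhouse. Sizes depended on the processing. LOC_Os03g32470, dim in NIES 72 h at a log2 level of 6.63, had 6.10 with an offset of 16 and 7.59 with Feature Extraction. LOC_Os01g47070 had −5.92 with Feature Extraction and −5.44 with median centring, and LOC_Os04g59150 had −4.94 and −5.24.

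This indirect comparison had the lowest correlation between dye orientations, 0.82, and a median technical standard error of 0.12. Higher loci made up 69.3% of its calls under loess, 27.2% of 301 calls under median centring and 20.2% of 1689 calls under median centring with a 2-fold mean, so the balance of direction was not settled. Without the Cy3 orientation 1570 loci passed the threshold. In the 6 comparisons Feature Extraction's log ratios gave between 1.67 and 4.22 times as many calls as normexp and loess, with 94.9 to 99.6% of the calls of the latter kept.

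Over the 24789 loci measured in any comparison, distances were formed between all 5 RNAs. Gamma 72 h and NIES 72 h were closest, with 764 loci at least 2-fold apart, followed by ITF 0 h and NIES 72 h with 1505. Gamma 6 h was the most distant RNA from NIES 0 h (6372 loci), ITF 0 h (5824) and NIES 72 h (4164), and lay 3345 loci from gamma 72 h. The gamma 72 h and NIES 72 h RNAs had the fewest loci apart, and NIES 0 h and gamma 6 h the most, in all 5 settings compared. By the SD of the log2 ratios gamma 72 h and NIES 72 h were closest in 4 of these, but with Feature Extraction's log ratios their SD of 1.07 was above that of NIES 0 h and ITF 0 h (1.02) and of ITF 0 h and NIES 72 h (1.03). Other distances moved: gamma 6 h and gamma 72 h were 6646 loci apart with median centring and a 2-fold mean and 6937 with Feature Extraction, and ITF 0 h and NIES 72 h 2425 and 4313.

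**Figure D3:**
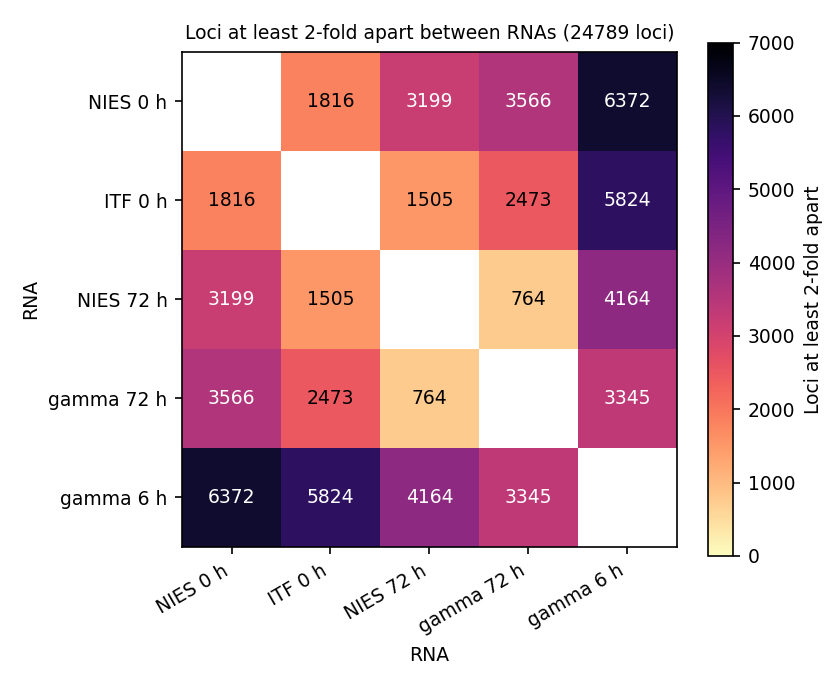
Number of loci at least 2-fold apart in both dye orientations for each pair of the 5 RNAs, over 24789 loci, where each axis lists the RNAs and colour and printed number give the count. Gamma 72 h and NIES 72 h are closest at 764 and NIES 0 h and gamma 6 h farthest apart at 6372.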

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

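The tests of unrelated RNAs with evenly split variance, of hybridisation noise and of the number of measured loci were chosen after the results were seen. The partner check and the tests on neighbouring loci were chosen before.

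Several named loci had opposite directions under the same contrast at the 2 sites or at the 2 times. None of these differences was tested, since each value comes from 1 RNA pair. Named loci are the extremes of the comparisons themselves. All those listed next for the 72 h changes except LOC_Os04g02880 were extremes of the derived comparisons between sites. Large differences between the sites follow from that choice. Between the 72 h changes at the farm and in the greenhouse, LOC_Os10g39150 differed by 8.42 on the log2 scale (3.52 and −4.90), LOC_Os11g32650 by 8.27 (6.99 and −1.27), LOC_Os04g02880 by 6.62 (0.36 and −6.26) and LOC_Os03g32470 by 5.82 (5.61 and −0.21). In the other direction, the difference was −7.70 for LOC_Os04g21350 (−2.36 and 5.35), −4.31 for LOC_Os04g59150 (−4.09 and 0.23) and −3.82 for LOC_Os01g47070 (−1.77 and 2.05). Some of these loci already differed between the 0 h RNAs, which enters the difference. In ITF 0 h over NIES 0 h, LOC_Os10g39150 had −5.21, LOC_Os11g32650 −3.30, LOC_Os04g02880 −5.55 and LOC_Os04g21350 4.69, all called. LOC_Os03g32470 (−0.27), LOC_Os04g59150 (0.08) and LOC_Os01g47070 (−0.83) were not called there. Between 6 h and 72 h at the farm, LOC_Os10g39150 differed by 4.93 (−1.41 and 3.52), LOC_Os07g37550 by 2.03 (−1.42 and 0.61) and LOC_Os03g39610 by 1.80 (−0.74 and 1.05). The values of 0.36, −0.21, 0.23, −1.42, 0.61, −0.74 and 1.05 did not reach 2-fold in both orientations.

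Probes without a locus identifier gave signal too: 53.5% of their spot channels were well above background, against 52.9% for probes with a locus and 0.0408% for negative controls. Lower and higher calls among them numbered 74 and 22 of 1073 in ITF 0 h, 123 and 35 of 1101 in NIES 72 h, 116 and 91 of 1236 in gamma 6 h, and 56 and 32 of 1103 in gamma 72 h. The derived comparisons had 41 lower and 85 higher (difference of 72 h changes) and 6 and 16 (indirect). With median centring, the larger side changed in gamma 6 h (48 lower and 113 higher). So it did in the difference (49 and 30) and in the indirect comparison (7 and 3). It stayed the lower one in ITF 0 h (50 and 10), NIES 72 h (93 and 36) and gamma 72 h (30 and 9).

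The ratios of ITF 0 h and NIES 72 h against NIES 0 h changed together. A partner of NIES 72 h that was in truth ITF 0 h, as 1 label field has it, would need a positive slope of that partner's level on the ratio of the 0 h RNAs, but the slope was −0.46 (−0.50 and −0.42), against the 0.49 and 0.47 of the references labelled ITF 0 h. Unrelated RNAs with evenly split variance gave a correlation of at most 0.52 in 100 simulations, below the 0.76 observed across loci. That bound holds for the even split only, and a shared RNA of larger spread would raise it. Were the 3 RNAs unrelated, NIES 0 h would hold 56.0% of the summed variance, NIES 72 h 44.7% and ITF 0 h −0.674%, which no variance can be. Unrelated RNAs with an even split therefore do not give these values. The number of shared calls, 1285 against 1339 simulated, cannot decide, since simulated calls needed only a 2-fold mean. Under that looser rule 69 calls in opposite directions were simulated, against 15 observed under the stricter rule. By the SD of the log2 ratios, ITF 0 h lay 0.631 from NIES 0 h and 0.563 from NIES 72 h. Those greenhouse RNAs were 0.851 apart, so ITF 0 h lay between them. A state of the NIES 0 h RNA or its plants, such as another sampling time of day, may account for part of the pattern. Such a state would not account for the distance between ITF 0 h and NIES 72 h. It was not tested, nor was the difference between the sites.

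The 6 h comparison had the most called loci. Hybridisation noise was not larger there: the SD over loci of the deviation of an orientation from the mean of both was 0.103 at 6 h and 0.145 at 72 h. More measured loci at 6 h did not account for it either, since over 18442 loci above background in both comparisons the share called was 29.0% at 6 h and 12.9% at 72 h, a ratio of 2.25. Exposure, transport, the field and the time of day of sampling remain open, because none of the arrays used here holds greenhouse RNA of 6 h and 1 RNA stands for each condition.

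Neighbouring loci on a chromosome were called together in the same direction more often than in random placements. At arrival 155 such pairs were seen against a mean of 81.8 and a highest of 112 in 1000 placements, and at 6 h 967 against 767 and 836. The lowest ratio over the 4 direct comparisons was 1.26, which argues against random placement among loci of like brightness. The median distance of their spots on the array was 0.95 to 1.04 times that of other neighbours (lowest at 6 h), above the 0.8 set in advance as the bound for an effect of position. Cross-hybridisation of near-identical neighbouring copies and local regulation cannot be told apart, since probe sequences were not used here and both would fade with distance, as seen in a highest ratio of 1.04 at 10 loci apart.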

How the results depend on the processing

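The combination of median centring with a 2-fold mean, and the alternatives of the 72 h overlap between sites and of the overlap against NIES 0 h, were chosen after seeing the data. Numbers of called loci are given in the order ITF 0 h, NIES 72 h, gamma 6 h, gamma 72 h, difference of 72 h changes, indirect 72 h comparison. A 1.5-fold threshold gave 4037, 6016, 9522, 5009, 5489 and 2044 loci and a 3-fold threshold 703, 1505, 3019, 1061, 1311 and 279, by construction. Feature Extraction's log ratio gave 3922, 6950, 9730, 6598, 6996 and 3233, and the values of the authors 3912, 6940, 9714, 6585, 6985 and 3229; the cause was not tested. Median centring gave 936 for ITF 0 h, 1206 for gamma 72 h and 301 for the indirect comparison. With the same centring and a 2-fold mean they had 2445, 3457 and 1689, which kept 92.8, 93.9 and 65.9% of the main calls. The smaller numbers under median centring thus depended on the rule of both orientations. Why the indirect comparison kept fewer was not tested. With 1 array left out, gamma 72 h had 2678 to 3897 loci. With 1 dye orientation of its 3 ratios left out, the indirect comparison had 914 to 1570. In both cases a single orientation then decides the call. All other alternatives run stayed within 1.5 times. The overlap of 6 h and 72 h calls was 897 under median centring and 4430 with Feature Extraction's ratio. The 72 h calls shared by both sites (1123) became 537, 2780 and 2770 under median centring, Feature Extraction and the authors' table, and the calls shared against NIES 0 h (1285) became 646, 2718 and 2713. Over all measured loci the label slopes were −0.45 (NIES 72 h), 0.49 (gamma 6 h) and 0.48 (gamma 72 h).

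With median centring and a 2-fold mean the share of higher calls was 30.3, 62.3, 77.8, 41.3, 30.4 and 20.2%, against 46.1, 48.3, 58.0, 56.8, 54.2 and 69.3%. That centring shifted the median log2 ratio by −0.07, 0.09, 0.21, −0.08, −0.17 and −0.28. Of the values of named loci under alternatives, 139 stayed within their spread, 53 moved and none changed sign. Among all called loci, 14 of the difference changed sign with Feature Extraction's ratio and 2 of the indirect comparison with separate-channel levels. Leaving out the filter on dim probes added no call, and the stricter filter kept 84.6 to 97.1% of the calls. The limit of 3 technical standard errors removed none, which says little. The median error was at most 0.12, far below a 2-fold change. Saturated spots (0) and several probes per locus did not occur, so those alternatives say nothing, and the alternatives for gene lists were not run because no list was matched. No paired analysis was possible because each comparison holds 1 RNA pair. Low signal limits dim loci: the median signal was at most 89 against a background of at least 57.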

Other observations

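The longest run of measured neighbouring loci called in 1 direction, chosen after its values were seen, held 10 loci from LOC_Os07g33870 to LOC_Os07g34006 on chromosome 7, all higher at 6 h with log2 ratios of 1.93 to 3.16. On chromosome 1, 4 neighbours ending in LOC_Os01g03340 were lower in NIES 72 h (−2.30 to −1.48) and lower in gamma 72 h (−5.67 to −3.35). These ranges have different references, NIES 0 h and ITF 0 h. All 4 loci had positive log2 ratios in ITF 0 h over NIES 0 h (2.75 for LOC_Os01g03340), and all but LOC_Os01g03330 were called there. That difference enters the gamma 72 h ratios. In the indirect comparison of gamma 72 h with NIES 72 h, only LOC_Os01g03340 among the 4 was called, as lower.

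Some loci moved one way at arrival and the other way afterwards. Of the loci measured in both, 528 were called in opposite directions in ITF 0 h over NIES 0 h and in gamma 6 h over ITF 0 h, and 451 in the same direction. Of the opposite calls, 301 were higher at arrival (100 in independent lists) and 227 lower (148). Of the same calls, 160 were higher in both (127) and 291 lower in both (117). LOC_Os01g03340 was 2.75 higher at arrival on the log2 scale and −5.69 at 6 h, and LOC_Os11g32650 was −3.30 at arrival and 6.77 at 6 h. Because ITF 0 h is the test of the first ratio and the reference of the second, unrelated RNAs with evenly split variance would give a correlation of −0.52. They would also give 2020 opposite calls, but under the looser rule of a 2-fold mean. The observed correlation across loci was −0.02.

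The NIES 72 h change was correlated with the 6 h change at the farm, with which it shares no RNA. The correlation across loci was 0.37, with 1480 calls in the same direction and 306 in opposite directions. Of the former, 647 were higher in both (240 in independent lists) and 833 lower in both (194). Of the latter, 190 were higher in NIES 72 h (181) and 116 lower (257).

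Median ratios differed between brightness classes in the mean of both orientations too, where an additive dye trend cancels. Brightness was the mean over all 8 arrays, and ITF 0 h RNA was on more of them than gamma 6 h RNA. For gamma 6 h over ITF 0 h, direction and class are therefore linked by how the classes were made. How much of the difference between classes comes from this was not tested. With median centring, the median log2 ratio of gamma 6 h over ITF 0 h was 0.15 among the dimmer 50% of measured loci, 0.48 among those between them and the brightest 10%, and 0.31 among the brightest 10%. Under loess the medians were 0.07, −0.02 and −0.33, so the median of the brightest loci changed sign between these normalisations. For the indirect comparison of gamma 72 h with NIES 72 h the medians were −0.09, −0.62 and −0.86 with median centring and 0.01, −0.06 and −0.05 under loess.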
